A study of Mus musculus with 10 samples.

How the data were processed

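RNA of muscle stem cells of male C57BL/6 mice, sorted as CD45-, CD31-, Sca1- and VCAM+ cells, was sequenced in 10 libraries, per the labels: 3 of fresh cells at 0 h, 3 of cells cultured for 24 h with DMSO (vehicle) and 4 of cells cultured for 24 h with 40 µM Tubastatin A, in medium with 10% horse serum. Each replicate was a single animal. Libraries were made from 5 ng RNA with SMART-Seq v4 and NuGEN Ovation kits and read as pairs of 150 bp. Per the submitters' processing notes, Trim Galore, STAR, featureCounts of Subread, edgeR and the build mm10 were used, without versions or settings.

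The deposited table holds RPKM (reads per kilobase of gene, relative to library size) for 12803 genes and 10 libraries, as computed by the authors. With union exon lengths of GENCODE M21, 12721 of its symbols (99.4%) could be matched, and multiplying RPKM by length and a single factor per library returned whole reads, within 0.05 reads in every library, for 12176 genes (95.1%). These factors gave the scaled library sizes the authors had used. Reads in the table over scaled size lay between 1.40 and 1.42 in fresh and between 0.83 and 0.93 in cultured libraries, so RPKM in this table are not relative to all reads. No value was exactly 0: 1793 values of 577 genes stood at a floor of the gene that takes the place of zeros, so the lowest levels are not measured levels. The table held 7 repeated symbols and 11 mitochondrial genes. The libraries held 37.8M to 55.6M reads in the table, and a single read in a gene of 1 kb corresponds to 0.016 to 0.0339 RPKM. Differences between replicates exceeded counting noise, with chi-square over degrees of freedom of recovered reads between 26.96 and 438.8.

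The design made before the data were examined assumed read counts. Because the values were RPKM, the fallback test it named was used: log2(RPKM + 1) was fitted for all 12803 genes with limma 3.58.1 in R 4.3.3, a trend of variance with level, and 1 model for the 3 groups. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 are called changed. The pseudocount of 1 RPKM understates the fold of genes with low levels. No gene was left out for low levels. The comparisons were vehicle against fresh, Tubastatin A against vehicle and Tubastatin A against fresh. The fit was tried on simulated data with 100 changed genes per size. In the order of the comparisons, it found 88%, 85% and 82% of changes of 1 log2 unit. It found 98%, 100% and 100% of changes of 2, with 5.1%, 4.1% and 2.7% of calls false. Changed genes were drawn from those with a mean log2(RPKM + 1) over 1, and errors were independent between genes. These rates thus do not cover genes of lower levels or data in which most genes change.

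The 34 gene lists were written before the data were examined, from general knowledge. The 33 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, which made 99 tests adjusted together, and again with a correlation estimated per list. Counts adjusted over the list alone use the adjusted p within that list. Libraries were placed on the axis from the fresh to the vehicle mean, each fresh or vehicle library on an axis made without it, and groups were compared with exact permutation tests. Overlaps of calls were set beside the product of both list sizes over the genes tested and were counted again with the shared libraries divided between both comparisons. Covariances were set beside 100 simulated sets, with Tubastatin A at vehicle levels or all groups at 1 level. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the figures.

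Genes to be named were fixed by a rule: per comparison the 10 highest and 10 lowest log2 changes among genes with adjusted p under 0.05, a mean log2(RPKM + 1) of at least 4, no overlap between the libraries of both groups and no predicted-gene symbol; up to 4 members with the lowest p per list and comparison; and always Hdac6, Pax7, Myod1, Myog, Mki67, Ccnd1, Calcr and Spry1. A gene named by the rule in any comparison may be given in another. Genes outside it were chosen after their values were seen and are named as such. Reads of near-identical genes, such as Hspa1a with Hspa1b and Hba-a1 with Hba-a2, may not be separable, and reads of overlapping or antisense genes may not be either, since use of strand is not stated.

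Alternatives were limma's voom on recovered reads of 11926 genes with a mean of at least 10 reads, with and without sample quality weights; other scalings (relative log expression, upper quartile, reads in the table alone, and reads without the mitochondrial and the 10 most abundant genes); filters on low levels; pseudocounts of 0.1 and 5; fits on only the groups compared; a block for the replicate number; reads thinned to the shallowest library; stricter thresholds; and each library left out. Voom without weights, some of the scalings and weights for lists, positions, overlaps and named genes, and list counts without a doubted library were chosen after seeing the data.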

Results

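Muscle stem cells of male C57BL/6 mice were profiled directly after sorting (fresh, n = 3), after 24 h in culture with the solvent DMSO (vehicle, n = 3) and after 24 h in culture with 40 µM Tubastatin A, an inhibitor of the tubulin deacetylase HDAC6 (n = 4), each library from a single animal. Unless stated otherwise, levels are mean RPKM ± SD over these libraries, and log2 changes, including values after rose by or fell by, are differences of log2(RPKM + 1) with their standard error (SE) and the adjusted p of the limma test over 12803 genes. The cells had been sorted as CD45-, CD31-, Sca1- and VCAM+ cells.

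In culture with vehicle, transcripts of stem cell quiescence fell and those of DNA replication and mitosis rose. Calcr, the calcitonin receptor that holds muscle stem cells out of the cell cycle, fell from 81.2 ± 23.0 to 1.17 ± 0.0483 RPKM, a log2 change of -5.20 (SE 0.19, adjusted p = 8.7e-10). Pax7, the transcription factor that marks these cells, fell from 22.4 ± 9.48 to 4.73 ± 0.609 RPKM, and Spry1, an inhibitor of growth factor signalling needed for quiescence, from 469.9 ± 142.6 to 29.6 ± 1.36 RPKM. Mcm2, a subunit of the replicative helicase, rose from 7.05 ± 0.884 to 80.4 ± 8.58 RPKM, and Ccnd1, the cyclin D1 of G1 phase, from 10.9 ± 3.84 to 45.8 ± 8.88 RPKM. Of the 12803 genes tested, 8580 differed between vehicle and fresh, 4096 higher and 4484 lower in vehicle, and 3916 of them differed at least 2-fold. Without fresh replicate 1, 8713 genes differed. The 34 gene lists were fixed beforehand, and 99 list tests were made over the 3 comparisons, of which 49 passed at a preset correlation and none with an estimated one.

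All 24 measured members of the quiescence list fell in culture, with a median log2 change of -2.60 (camera adjusted p = 7.6e-10; adjusted p = 0.17 with an estimated correlation). Chrdl2, a secreted antagonist of bone morphogenetic proteins, fell by 7.52 on the log2 scale (SE 0.18), to 0.728 ± 0.135 RPKM. Most Notch list genes are also in the quiescence list: Calcr, Heyl, Hey1, Hes1, Notch1, Notch2, Notch3, Col5a1 and Col5a3. In every comparison both lists therefore largely count the same genes. The Notch list fell in 11 of 11 measured members (adjusted p = 2.2e-05, and adjusted p = 0.35 with an estimated correlation). Among its members were Heyl and Hey1, transcriptional repressors induced by Notch, at 6.34 ± 0.289 and 3.76 ± 0.312 RPKM in vehicle against 232.7 ± 49.2 and 54.4 ± 8.97 RPKM in fresh cells, and Col5a1, a collagen chain under Notch control. Of the 14 myogenic regulators, 1 rose, 6 fell and 7 did not pass the test (adjusted p = 0.18). Myf5, a factor that commits cells to the muscle lineage, fell from 248.4 ± 30.7 to 34.1 ± 2.21 RPKM, and Id3, an inhibitor of such factors, fell by 2.05 on the log2 scale, whereas Met, the receptor for hepatocyte growth factor, rose by 2.14. Myod1, the activation factor of muscle stem cells, measured 756.9 ± 426.2 RPKM in fresh and 1186 ± 101.1 RPKM in vehicle cells and did not pass (adjusted p = 0.076). Its fresh libraries lay at 271.7, 1071 and 927.9 RPKM, and without fresh replicate 2 or fresh replicate 3 the rise passed, at 1.23 and 1.13. Myog, the factor of terminal differentiation, measured 83.5 ± 14.0 and 15.4 ± 4.50 RPKM and did not pass either (SE 1.28, adjusted p = 0.12). The variance is shared by the 3 groups. Without Tubastatin A replicate 2, where Myog stood at 195.2 RPKM, its log2 change of -2.39 passed (SE 0.21, adjusted p = 2.2e-06). Of the 20 measured genes of muscle differentiation, 1 rose and 4 fell, and none rose and 4 fell adjusted over the list alone. Without that library 1 rose and 10 fell. Among those that fell were Des, the muscle intermediate filament desmin, and Cdkn1a, the cell cycle inhibitor p21.

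Cell cycle genes made up the largest groups that rose in culture. In the S phase list 41 of 42 members rose, with a median log2 change of 2.14 (adjusted p = 3.1e-17; adjusted p = 0.14 with an estimated correlation), and 41 also adjusted over the list alone. Uhrf1, which carries DNA methylation through replication, rose from 6.27 ± 1.05 to 95.5 ± 7.08 RPKM. Cdc6, a licensing factor of replication origins, rose from 1.25 ± 0.122 to 25.8 ± 4.72 RPKM, and Exo1, a DNA exonuclease, from 0.227 ± 0.0931 to 7.26 ± 0.859 RPKM. In the G2/M list 47 of 53 measured members rose and 1 fell (adjusted p = 5.7e-13; adjusted p = 0.28 with an estimated correlation). They included Cdk1, the mitotic kinase, at 22.7 ± 4.60 RPKM after culture, Aurkb, the kinase of the chromosomal passenger complex, Gtse1, a microtubule-binding protein of G2, and Mki67, the proliferation antigen, which rose by 1.59 to 5.27 ± 0.438 RPKM. Of the 14 regulators of G1 entry 11 rose and 3 fell (adjusted p = 0.0021; adjusted p = 0.14 with an estimated correlation). Ccne2, a cyclin E, rose by 3.65, Cdk6, a partner of cyclin D, by 2.49 and E2f1, a transcription factor of S phase entry, by 2.45. The list of cyclin-dependent kinase inhibitors also holds Rb1, Rbl1 and Rbl2 of the retinoblastoma family. Of its 10 genes, 2 rose and 5 fell (adjusted p = 0.51). Among them Cdkn1c, the inhibitor p57, fell from 93.2 ± 27.6 to 1.77 ± 0.292 RPKM, and Cdkn2d fell with a log2 change of -2.63, whereas Rbl1, a retinoblastoma relative, rose by 2.41.

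Transcripts of biosynthesis rose with them. Of the 30 genes of ribosome biogenesis 22 rose and 2 fell, 24 and 2 adjusted over the list alone (adjusted p = 2.2e-05; adjusted p = 0.40 with an estimated correlation), with Dkc1, which modifies ribosomal RNA, at 87.3 ± 3.40 against 25.9 ± 1.53 RPKM, and Bop1, a ribosome assembly factor. Of the 28 measured genes of oxidative phosphorylation 18 rose and 1 fell (adjusted p = 0.0026; adjusted p = 0.71 with an estimated correlation), among them Sdhd of complex II and Cyc1 of complex III. Of the 20 genes of cholesterol synthesis 13 rose and none fell (adjusted p = 0.0012; adjusted p = 0.51 with an estimated correlation), with Mvd, the mevalonate decarboxylase, at 58.6 ± 9.47 against 8.15 ± 3.10 RPKM. Of the 18 glycolysis genes 9 rose and 7 fell (adjusted p = 0.33), among them Eno1, an enolase, which rose by 2.39, and Slc16a3, a lactate transporter, which fell with a log2 change of -3.02. Among genes with a mean log2(RPKM + 1) of at least 4, the 10 with the largest rise included Asns, the asparagine synthetase, from 3.91 ± 2.29 to 93.4 ± 6.26 RPKM, G6pdx, the entry enzyme of the pentose phosphate pathway, from 5.54 ± 0.685 to 79.7 ± 2.33 RPKM, and Gsr, the glutathione reductase, from 10.6 ± 0.948 to 118.7 ± 2.34 RPKM. Slc48a1, a haem transporter, Isyna1, which makes inositol phosphate, Acot7, a thioesterase, and Dnph1, a nucleotide hydrolase, rose by 3.68, 3.31, 3.59 and 3.86.

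Transcripts of acute stress and of the matrix had the highest levels in fresh cells. Of 20 measured immediate early genes 19 fell in culture, with a median log2 change of -5.15 (adjusted p = 5.4e-11; adjusted p = 0.17 with an estimated correlation). Fos, a subunit of AP-1, fell from 3757 ± 2265 to 7.15 ± 0.301 RPKM, Atf3, a stress-induced transcription factor, from 1109 ± 277.0 to 1.67 ± 0.331 RPKM, and Fosb, Klf4, Nr4a1 and Zfp36 fell with them. Of the 15 heat shock genes 12 fell and none rose (adjusted p = 7.4e-05; adjusted p = 0.40 with an estimated correlation), including Dnajb1 and Bag3, which work with the chaperone HSP70. Hspa1a and Hspa1b, which encode that chaperone, fell with log2 changes of -9.96 and -9.15, and reads of this near-identical pair may be assigned to either gene. Fresh replicate 1 stood apart here, with 17.9% of its reads in both lists together against 10.0% and 9.24% in the other fresh libraries, and with Fos at 6344 RPKM against 2789 and 2137. It lay at least 2-fold above both other fresh libraries in 48 genes and below both in 74, against 16 and 31 for replicate 2 and 10 and 8 for replicate 3. Vehicle libraries held 1.63% to 1.68% there. Of 18 measured NF-kB and cytokine genes 16 fell and 1 rose (adjusted p = 1.1e-06; adjusted p = 0.14 with an estimated correlation), with Cxcl1, a neutrophil chemokine, at 5.17 ± 0.844 against 1073 ± 374.1 RPKM, and with Icam1, an adhesion molecule, and Il6, an interleukin, among those that fell. Of 17 genes of the integrated stress and unfolded protein response 13 fell and 4 rose (adjusted p = 0.031; adjusted p = 0.67 with an estimated correlation): Herpud1, a component of protein degradation at the endoplasmic reticulum, and Ddit3, the stress factor CHOP, fell with log2 changes of -4.77 and -2.76, and Phgdh, an enzyme of serine synthesis, rose by 2.48. Of the 23 autophagy and lysosome genes 18 fell and 2 rose (adjusted p = 6.8e-04; adjusted p = 0.36 with an estimated correlation), with Sqstm1, the autophagy receptor p62, at 177.4 ± 6.02 against 1611 ± 382.0 RPKM, and with Map1lc3a and Ctsb also lower. Of 23 measured matrix genes 21 fell and 2 rose (adjusted p = 9.4e-06; adjusted p = 0.47 with an estimated correlation), with Col6a1, a collagen VI chain, at 2.60 ± 0.697 against 203.2 ± 65.1 RPKM. Nppc, a natriuretic peptide, Tnfaip6, a hyaluronan-binding protein, Chodl, a membrane lectin, and Serping1, a complement inhibitor, were among the 10 with the largest fall at mean levels of at least 4 on the log2 scale.

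Markers of other cell types of muscle also had their highest levels in fresh libraries. In culture 9 of 9 endothelial, 5 of 5 immune, 10 of 11 fibro-adipogenic progenitor, 6 of 7 tenocyte, 7 of 9 pericyte and smooth muscle, 4 of 5 Schwann cell and 8 of 12 mature myofibre markers fell, and 1 tenocyte marker rose. These lists passed with adjusted p between 2.2e-05 and 0.026, and with adjusted p between 0.12 and 0.67 with an estimated correlation. Gsn, the actin-severing gelsolin, stood at 1362 ± 68.4 RPKM in fresh and 34.7 ± 4.11 RPKM in vehicle cells, Pecam1, the endothelial CD31, at 5.61 ± 1.39 and 0.281 ± 0.146 RPKM, and Lyz2, a lysozyme of myeloid cells, at 4.17 ± 0.971 and 0.0144 ± 0.00513 RPKM. Both measured erythroid markers fell, with Hba-a1, a globin, at 4.64, 17.4 and 4.64 RPKM in the fresh libraries, and reads of Hba-a1 may also come from its near-identical partner Hba-a2. Dcn, Fmod and Rgs5, markers of fibroblasts, tendon cells and pericytes, fell with log2 changes of -4.38, -4.40 and -3.02.

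The remaining lists showed mixed directions in this comparison. Of 40 primary cilium genes 10 rose and 13 fell (adjusted p = 0.75), and of 8 genes of cilium disassembly 6 rose and 1 fell (adjusted p = 0.077). Arl13b, a small GTPase of the cilium, fell from 58.8 ± 17.8 to 3.70 ± 0.273 RPKM. Nedd9, a scaffold of that process, fell with a log2 change of -2.82, and Aurka, Plk1 and Nek2, kinases of both cilium loss and mitosis, rose by 2.38, 2.92 and 1.68. Of 10 measured Hedgehog genes 2 rose and 6 fell, 3 and 6 adjusted over the list alone (adjusted p = 0.50), with Gas1, a Hedgehog co-receptor that is also in the quiescence list, at 63.7 ± 5.77 against 609.5 ± 287.8 RPKM. Of 14 deacetylase and tubulin acetylation genes 3 rose and 6 fell (adjusted p = 0.36), among them Sirt2, a tubulin deacetylase, Hdac4 and Hdac11, which fell with log2 changes of -2.13, -1.87 and -2.01. Hdac6 itself stood at 7.69 ± 0.916, 6.16 ± 0.313 and 6.60 ± 0.717 RPKM in fresh, vehicle and Tubastatin A cells, and it passed in none of the 3 comparisons (adjusted p = 0.074 for vehicle against fresh). Of 13 tubulins 5 rose and 4 fell (adjusted p = 0.50), with Tubb5 and Tuba1b higher and Tubb4a lower. Of 21 translation factors 12 rose and 4 fell (adjusted p = 0.23), with Eif1a lower. Without fresh replicate 1, 10 rose and 7 fell. Of 18 measured genes of fatty acid oxidation 2 rose and 10 fell (adjusted p = 0.47), with Pdk4, a brake on glucose oxidation, lower. Of 18 p53 targets 7 rose and 7 fell (adjusted p = 0.96), with Ccng1 higher and Fas, a death receptor, lower.

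The split into higher and lower genes depended on how the libraries were scaled. Relative to the authors' scaling, scaling by the reads in the table alone shifted all genes by 0.609 on the log2 scale in vehicle against fresh, and 6365 genes were then higher and 2905 lower. Without the 10 most abundant and the mitochondrial genes the split was 5815 higher and 3192 lower. With reads alone, 9 genes of fatty acid oxidation were higher and 2 lower, 19 primary cilium genes higher and 7 lower, and 5 deacetylase and tubulin acetylation genes higher and 3 lower, each against the direction above, while the lists called above kept theirs. The 3 fresh and the 3 vehicle libraries did not overlap for 67.6% of genes, where 10.0% would do so by chance. Splits of these 6 libraries number only 10, the real one included, too few to set a p of 0.05.

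**Figure D1:**
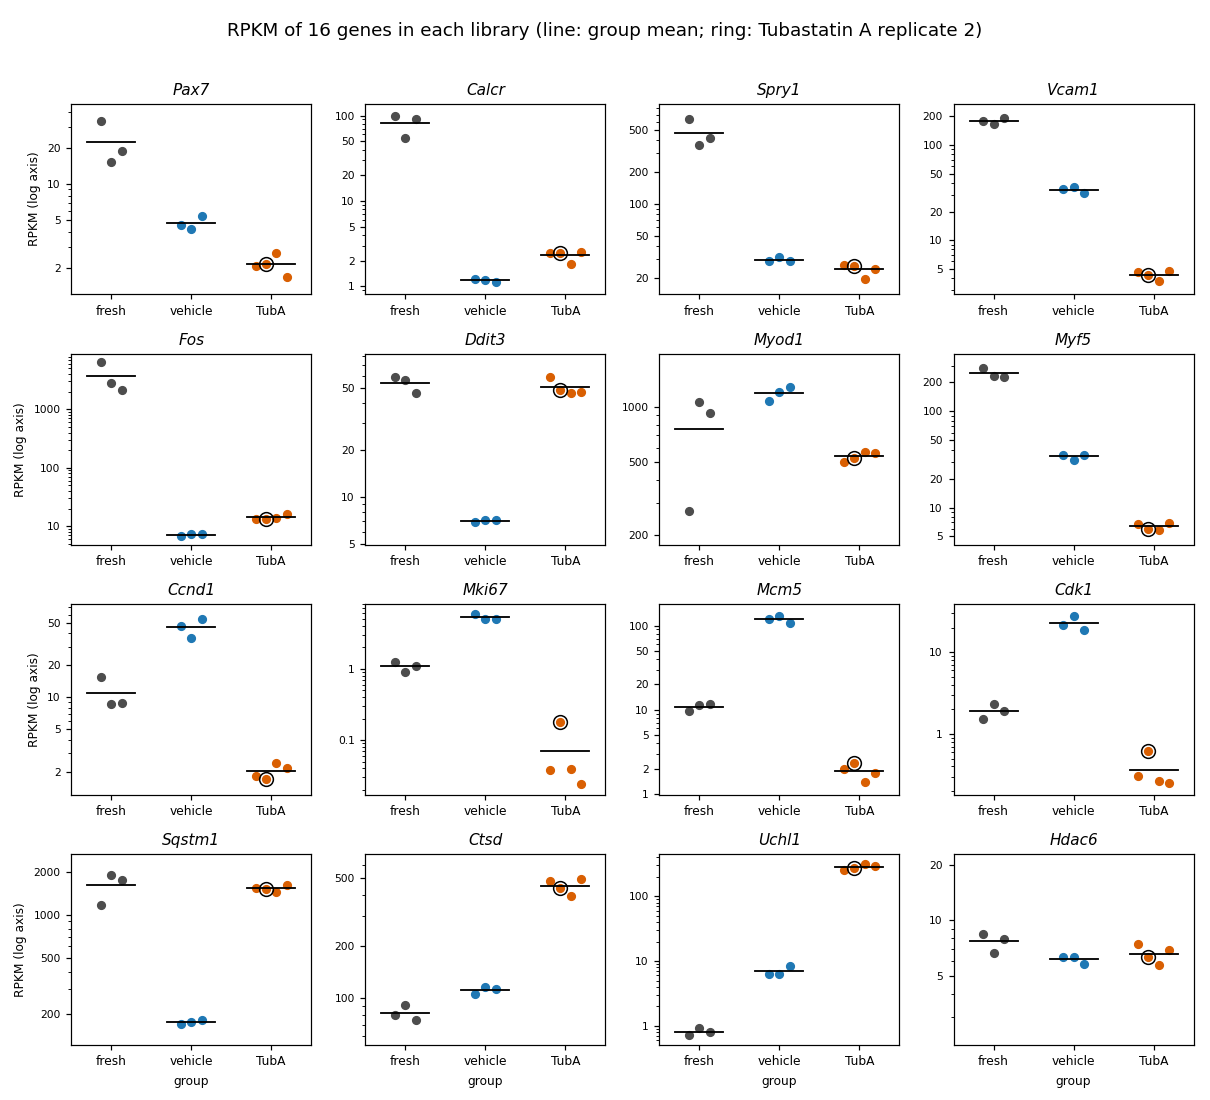
RPKM of 16 genes on log axes, 1 point per library of the fresh, vehicle and Tubastatin A (TubA) groups, with a line at each group mean and a ring around Tubastatin A replicate 2. Mcm5 stood at 118.6 RPKM in vehicle and 1.86 RPKM in Tubastatin A cells on average, whereas Calcr stayed at 1.17 and 2.32 RPKM, far below its 81.2 RPKM in fresh cells.

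With Tubastatin A, cell cycle transcripts were far lower than with vehicle, while Vcam1, Cd34 and Fgfr4 fell and transcripts of autophagy, of stress and of Uchl1 rose. Mcm5, a subunit of the replicative helicase, fell from 118.6 ± 11.6 RPKM in vehicle to 1.86 ± 0.394 RPKM in Tubastatin A cells, a log2 change of -5.39 (SE 0.13, adjusted p = 2.7e-10). Ccnd1 fell from 45.8 ± 8.88 to 2.03 ± 0.327 RPKM and Mki67 from 5.27 ± 0.438 to 0.070 ± 0.0724 RPKM. Uchl1, a ubiquitin hydrolase best known from neurons, rose from 7.03 ± 1.16 to 284.8 ± 29.6 RPKM, a log2 change of 5.16 (SE 0.12, adjusted p = 2.7e-10). In all, 7594 genes differed, 3796 higher and 3798 lower with Tubastatin A, and 2402 of them differed at least 2-fold.

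All 42 members of the S phase list fell, with a median log2 change of -2.91 (adjusted p = 4.0e-24; adjusted p = 0.12 with an estimated correlation), all 42 also adjusted over the list alone and under every scaling tried. Uhrf1 and Cdc6 fell with log2 changes of -5.14 and -4.60, and Rrm2, a subunit of ribonucleotide reductase, from 311.2 ± 60.8 to 15.8 ± 3.40 RPKM. The helicase subunits Mcm3, Mcm4, Mcm6 and Mcm7 had log2 changes between -3.96 and -3.28. They were among the 10 with the largest fall of the genes with a mean log2(RPKM + 1) of at least 4. In the G2/M list 47 of 53 members fell and 2 rose (adjusted p = 7.5e-20; adjusted p = 0.17 with an estimated correlation). Cdk1, Aurkb and Birc5, the mitotic inhibitor of apoptosis survivin, fell with log2 changes of -4.11, -4.64 and -3.85, and Hmgb2, a chromatin protein of dividing cells, from 80.2 ± 11.6 to 7.13 ± 1.17 RPKM. Of the 14 regulators of G1 entry 12 fell and 1 rose (adjusted p = 9.4e-06; adjusted p = 0.12 with an estimated correlation), with E2f1, Ccne1, Ccne2 and Cdk2 lower at log2 changes of -3.57, -3.68, -4.39 and -2.51. Of the 10 genes of the cyclin-dependent kinase inhibitor list 5 rose and 2 fell (adjusted p = 0.57). Cdkn1c rose from 1.77 ± 0.292 to 13.8 ± 3.02 RPKM and Cdkn2b, the inhibitor p15, by 1.11, while Rbl1 fell with a log2 change of -2.03. Cdkn1a measured 138.1 ± 16.1 and 113.0 ± 26.3 RPKM and did not pass (adjusted p = 0.16), and without Tubastatin A replicate 2 it did, at -0.45. Tubastatin A replicate 2 also held the highest level of some cell cycle genes in its group, with Plk1 at 1.82 RPKM against 0.502 to 0.697 and Mki67 at 0.178 against 0.0241 to 0.0395.

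Of the 24 quiescence genes 11 rose, 6 fell and 7 did not pass (adjusted p = 0.71), and their median log2 change was 0.25 but their mean was -0.02. Those that fell included Vcam1, the adhesion molecule used in the sort, from 34.0 ± 2.24 to 4.36 ± 0.417 RPKM, Cd34, a surface sialomucin, from 30.9 ± 1.28 to 3.47 ± 0.582 RPKM, Fgfr4, a growth factor receptor, and Gas1, which fell by 3.16 on the log2 scale. Pax7 fell from 4.73 ± 0.609 to 2.14 ± 0.399 RPKM (log2 change -0.87, SE 0.22, adjusted p = 0.0045). Calcr rose by 0.61 to 2.32 ± 0.322 RPKM (adjusted p = 0.012), and Spry1 measured 24.0 ± 3.20 RPKM against 29.6 ± 1.36 RPKM without passing (adjusted p = 0.17). Of the 11 measured Notch genes 7 rose and none fell (adjusted p = 0.070), among them Heyl, Jag1, a Notch ligand, Col5a1 and Col5a3, which rose by 0.61, 0.96, 1.12 and 1.88. Of the 14 myogenic regulators 9 fell and 1 rose (adjusted p = 0.030; adjusted p = 0.18 with an estimated correlation). Myf5 fell from 34.1 ± 2.21 to 6.37 ± 0.542 RPKM, Id2 fell, as did Id1 and Id3, inhibitors of such factors, with log2 changes of -1.45 and -1.53, and Myod1 fell to 539.2 ± 29.9 RPKM (log2 change -1.13, SE 0.38, adjusted p = 0.022), a call lost without vehicle replicate 2 or vehicle replicate 3.

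Genes of muscle differentiation separated 1 Tubastatin A library from the rest. Myog measured 1.99, 195.2, 1.68 and 2.05 RPKM in Tubastatin A replicates 1 to 4 and did not pass against vehicle (adjusted p = 0.53), whereas without replicate 2 it fell with a log2 change of -2.45 (SE 0.21, adjusted p = 3.9e-06). Replicate 2 exceeded each of the other 3 libraries at least 2-fold in 81 genes, against 1 to 6 such genes for the other Tubastatin A libraries, and 23 of the 81 belonged to the differentiation and myofibre lists. Of 20 measured differentiation genes 1 rose and 1 fell over all 4 libraries, none rose and 1 fell adjusted over the list alone (adjusted p = 0.77), and 1 rose and 4 fell without replicate 2. Desmin had a log2 change of -1.13 with all 4 libraries and of -1.18 without replicate 2, and passed both times. Of 12 mature myofibre markers 1 fell, and none adjusted over the list alone (adjusted p = 0.91), and 3 fell without replicate 2. Acta2, the smooth muscle actin, fell from 211.9 ± 33.7 to 23.0 ± 25.1 RPKM with replicate 2 at 60.8 RPKM, and Scx, a tendon transcription factor, fell with a log2 change of -3.96.

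**Figure D2:**
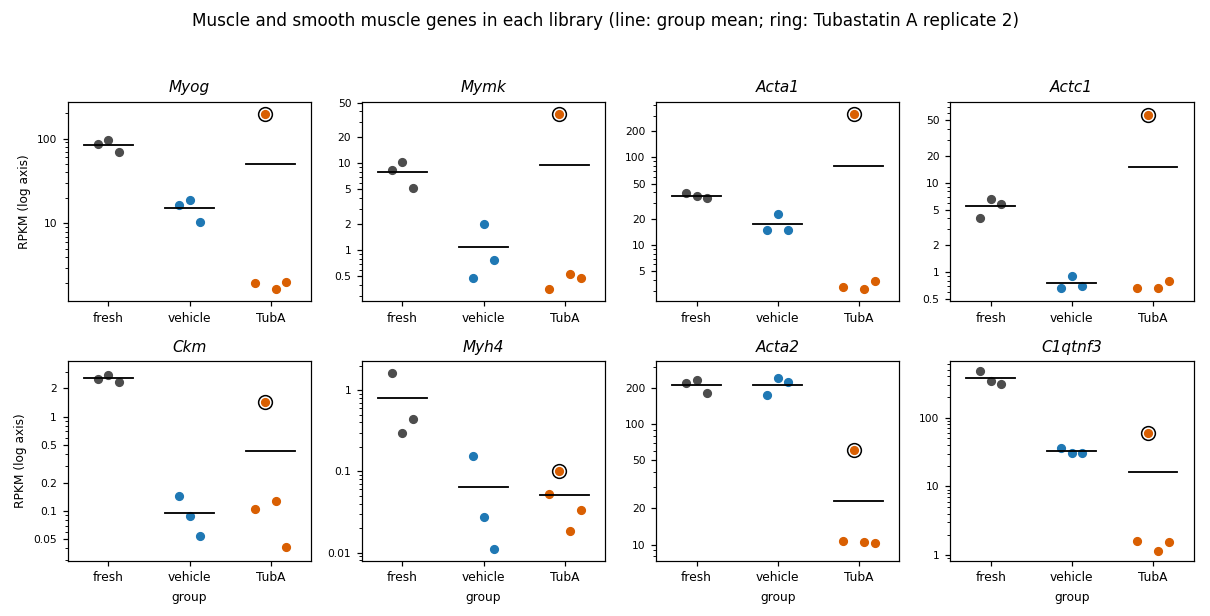
RPKM of 8 genes of muscle, smooth muscle and matrix on log axes, 1 point per library, with a line at each group mean and a ring around Tubastatin A replicate 2. Replicate 2 held 195.2 RPKM of Myog and 311.0 RPKM of the actin Acta1 but only 0.101 RPKM of the adult myosin Myh4; Mymk, Acta1, Actc1, Ckm and Myh4 were chosen after their values were seen.

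Autophagy and lysosome genes rose together with Tubastatin A: 22 of 23 members were higher and none lower (adjusted p = 2.0e-07; adjusted p = 0.17 with an estimated correlation), 22 also adjusted over the list alone. Sqstm1 rose from 177.4 ± 6.02 to 1529 ± 76.1 RPKM, Gabarapl1, an autophagosome protein, from 33.5 ± 4.55 to 245.4 ± 12.4 RPKM, and Ctsd and Ctsb, lysosomal cathepsins, by 2.01 and 1.90. Of 17 genes of the integrated stress and unfolded protein response 12 rose and 1 fell (adjusted p = 0.0035; adjusted p = 0.51 with an estimated correlation), with Ddit3 at 50.4 ± 5.88 against 7.07 ± 0.0965 RPKM, Chac1, a glutathione-degrading enzyme, higher by 1.80, and Hspa5, the chaperone BiP, at 1972 ± 486.0 against 314.0 ± 35.5 RPKM. Of 20 measured immediate early genes 14 rose and 1 fell (adjusted p = 0.0012; adjusted p = 0.50 with an estimated correlation), led by Ier3, which rose from 5.80 ± 1.51 to 127.5 ± 11.8 RPKM, Atf3 by 3.12 and Dusp1, a phosphatase of MAP kinases, by 2.12. Of the 15 heat shock genes 6 rose and 1 fell (adjusted p = 0.031; adjusted p = 0.67 with an estimated correlation), with Hspb8, a small heat shock protein, at 129.4 ± 5.73 against 14.3 ± 2.02 RPKM. Bag3, a partner of HSPB8 in selective autophagy, rose by 1.85, and Hspa1b and Hspa1a, of the near-identical pair, by 4.45 and 3.31. Gdf15, a stress cytokine, and Gadd45a, a stress sensor, rose by 3.73 and 3.35. At mean levels of at least 4 on the log2 scale, the largest rises also included Htra1, a serine protease, Sord, the sorbitol dehydrogenase, Mapre3, a microtubule end-binding protein, Mllt11 and Tcp11l2, higher by between 3.37 and 4.09.

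Biosynthetic groups fell. Of the 20 cholesterol synthesis genes 18 fell and none rose, 19 adjusted over the list alone (adjusted p = 8.7e-07; adjusted p = 0.36 with an estimated correlation), with Idi1, an isomerase of the pathway, at 7.87 ± 1.07 against 48.2 ± 4.02 RPKM, and with Fdps and Mvd lower at log2 changes of -2.19 and -2.03. Of the 30 ribosome biogenesis genes 29 fell (adjusted p = 1.8e-06; adjusted p = 0.36 with an estimated correlation), including Dkc1, Bop1 and Nop10. Of the 28 measured genes of oxidative phosphorylation 21 fell and none rose (adjusted p = 5.4e-04; adjusted p = 0.67 with an estimated correlation), including Ndufs3 of complex I. Of the 21 translation factors 9 fell and none rose (adjusted p = 0.057), including Eef1b2. Of the 8 genes of cilium disassembly 5 fell and none rose (adjusted p = 0.019; adjusted p = 0.36 with an estimated correlation), and these included Aurka, Plk1 and Nek2, lower at log2 changes of -3.35, -3.32 and -2.92, which are mitotic kinases too. Lgals1, a galectin, fell from 2134 ± 396.7 to 200.2 ± 26.4 RPKM, and Emp3, a membrane protein, and Dapk2, a death-associated kinase, fell with log2 changes of -3.33 and -3.88.

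In the remaining lists members moved both ways. Of the 13 tubulins 6 rose and 5 fell (adjusted p = 0.96): Tubb4a, a beta-tubulin typical of neurons, rose from 1.23 ± 0.328 to 34.5 ± 5.07 RPKM and Tuba8 rose by 1.34, while Tubb5 and Tuba1b fell with log2 changes of -1.76 and -1.27. Of the 14 deacetylase and tubulin acetylation genes 4 rose and 4 fell (adjusted p = 0.98), with Sirt2 at 35.4 ± 2.08 against 14.9 ± 1.73 RPKM, Hdac4 higher by 0.62 and Atat1, the tubulin acetyltransferase, lower at a log2 change of -0.79. Of the 40 primary cilium genes 9 rose and 10 fell (adjusted p = 0.91), with Bbs4, of the ciliary trafficking complex, and Kif3a, a motor of ciliary transport, higher by 1.29 and 0.87. Of the 10 measured Hedgehog genes 1 rose and 4 fell (adjusted p = 0.45). Of 23 measured matrix genes 9 rose and 6 fell (adjusted p = 0.80): Nid1, a basement membrane protein, rose by 2.15, while Tnc, a matrix protein of regenerating muscle, fell from 39.7 ± 4.19 to 0.776 ± 0.188 RPKM and Bgn, a proteoglycan, fell with a log2 change of -2.07. Of 18 measured NF-kB and cytokine genes 1 rose and 8 fell (adjusted p = 0.11), with Icam1 higher by 2.22 and Ccl2, Ccl7 and Bcl3 lower at log2 changes of -2.37, -2.60 and -1.69. Of the 18 glycolysis genes 6 rose and 5 fell (adjusted p = 0.96), with Slc2a1, a glucose transporter, higher by 1.63 and Ldha, a lactate dehydrogenase, lower at a log2 change of -1.10. Of the 18 measured genes of fatty acid oxidation 5 rose and 5 fell (adjusted p = 0.79), with Acadvl and Hadh, enzymes of beta-oxidation, higher by 1.78 and 1.03. Of the 18 p53 targets 9 rose and 6 fell, 9 and 7 adjusted over the list alone (adjusted p = 0.79), with Plk2 lower. Without Tubastatin A replicate 2, p53 targets had 6 higher and 7 lower and glycolysis genes 4 and 5.

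No tested list of markers of other cell types passed between the cultures, but single markers changed in both directions. In the endothelial list 1 of 9 fell, and none adjusted over the list alone; 1 of 5 immune markers rose, Cd68 of lysosomes, by 1.16; 3 of 11 fibro-adipogenic markers rose and 2 fell; 2 of 7 tenocyte markers rose and 1 fell. Of the 9 pericyte and smooth muscle markers 2 rose and 2 fell, of the 5 Schwann cell markers 2 rose and 2 fell, and of the 2 measured erythroid markers none passed. These lists, apart from the untested erythroid one, had adjusted p between 0.47 and 0.96. Cd55, Gsn and Mcam rose by 1.39, 1.46 and 1.28, and Col3a1, a fibrillar collagen, and Pmp22, a myelin protein, fell with log2 changes of -2.40 and -1.57.

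Median and mean log2 change also differed in sign for glycolysis (-0.01 and 0.02), the primary cilium (-0.02 and 0.04), tubulins (-0.15 and 0.19), matrix (0.18 and -0.05), tenocyte (0.11 and -0.22) and pericyte genes (0.03 and -0.25), and the camera direction was down for deacetylases and tubulin acetylation although their median was 0.02.

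Against vehicle, the scaling by reads alone moved all genes by only 0.079, with 4328 higher and 3570 lower, and upper quartile factors gave 4349 and 3331. The primary cilium list then had 13 higher and 9 lower with reads alone, but no list called above turned its direction. Without Tubastatin A replicate 2, 6995 genes passed, 3453 higher and 3542 lower. Only 1 of the 35 splits of these 7 libraries gave as many genes, the real split, and the highest other split gave 27. The libraries of both groups did not overlap for 68.6% of genes, where 5.70% would do so by chance.

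**Figure D3:**
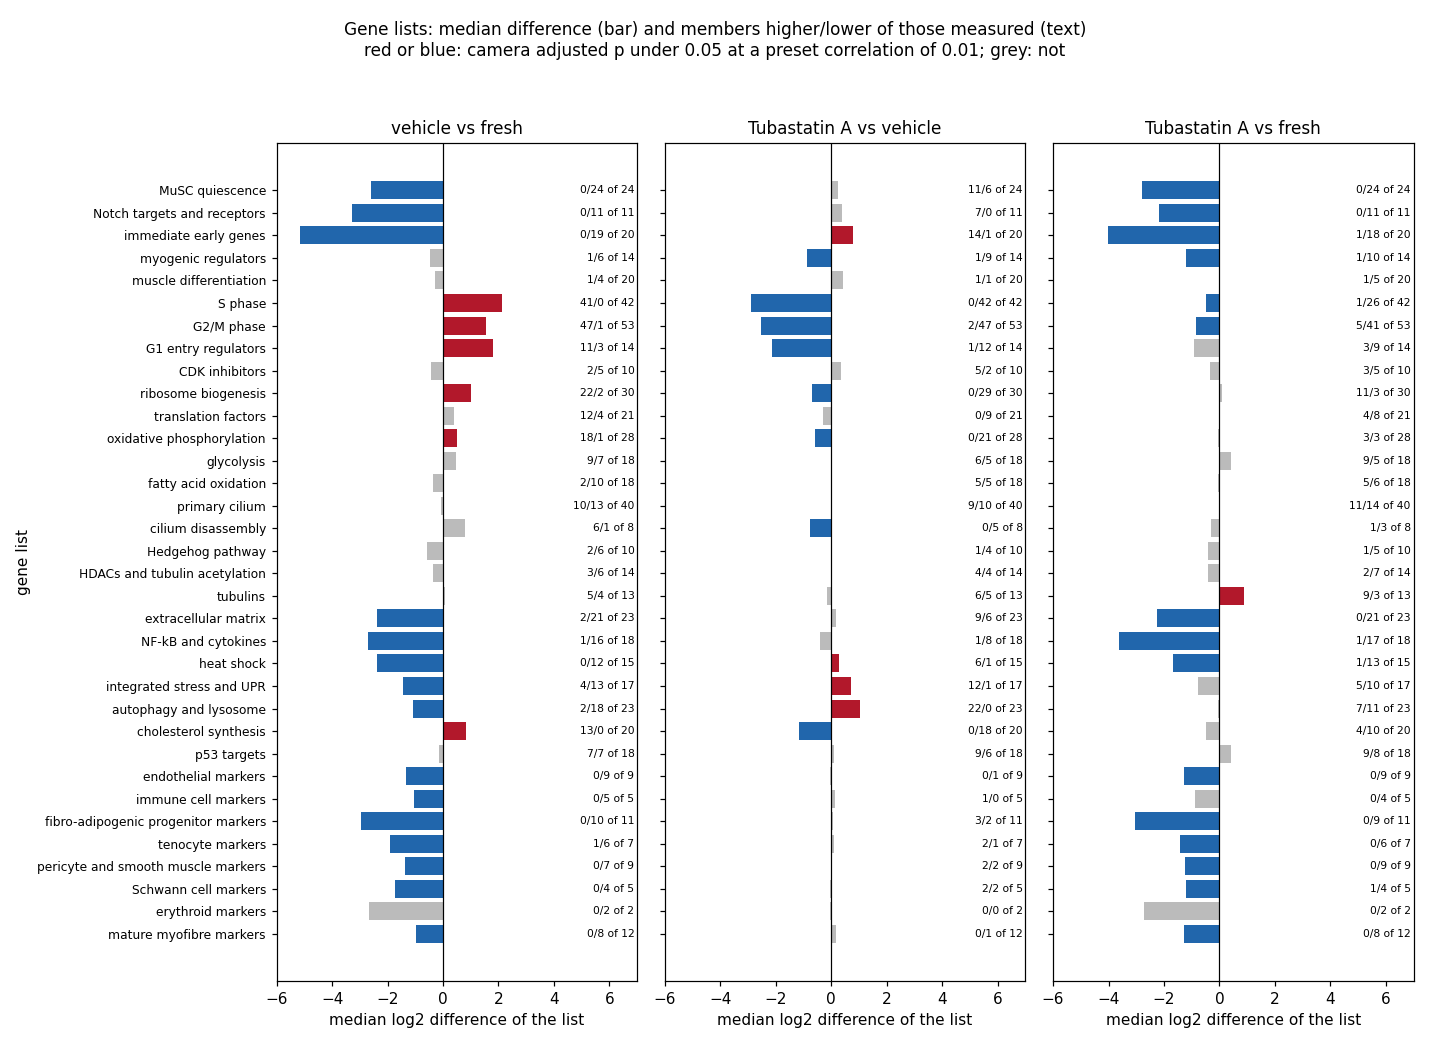
Median log2 difference of each gene list (bars) in the 3 comparisons, with the numbers of members higher and lower of those measured; red and blue bars passed the camera test at a preset correlation, and none of the 49 passed with an estimated one. The S phase list had 41 of 42 members higher in vehicle than in fresh cells and 42 of 42 lower in Tubastatin A than in vehicle cells, while for Tubastatin A against fresh the directions of autophagy, cholesterol, cilium, fatty acid oxidation and translation genes turned when libraries were scaled by reads alone.

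Against fresh cells, Tubastatin A cultures kept low levels of quiescence genes and also had low levels of cell cycle genes. All 24 quiescence genes were lower than in fresh cells, with a median log2 change of -2.80 (adjusted p = 9.3e-11; adjusted p = 0.16 with an estimated correlation), all 24 also adjusted over the list alone. Vcam1 stood at 4.36 ± 0.417 RPKM against 180.2 ± 13.7 RPKM (log2 change -5.08, SE 0.10, adjusted p = 2.6e-11), and Pax7, Calcr and Spry1 fell with log2 changes of -2.83, -4.59 and -4.20. Uchl1 rose from 0.813 ± 0.0982 to 284.8 ± 29.6 RPKM, a log2 change of 7.30 (SE 0.12, adjusted p = 5.1e-12). In all, 8314 genes differed, 3811 higher and 4503 lower, and 3062 of them differed at least 2-fold.

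Of the 42 S phase genes 26 fell, 1 rose and 15 did not pass (adjusted p = 0.0023; adjusted p = 0.51 with an estimated correlation), and with reads alone as the scaling 16 were lower and 9 higher. Mcm4 and Mcm5 stood at 8.34 ± 1.42 and 1.86 ± 0.394 RPKM against 41.0 ± 6.32 and 10.9 ± 1.16 RPKM in fresh cells. Of 53 measured G2/M genes 41 fell and 5 rose, 42 and 5 adjusted over the list alone (adjusted p = 2.8e-05; adjusted p = 0.51 with an estimated correlation), including Smc4, a condensin subunit, Tacc3, a spindle protein, and Hmgb2, lower at log2 changes of -2.24, -2.12 and -2.29. Mki67 and Ccnd1 were lower at log2 changes of -0.96 and -1.94. Of the 14 regulators of G1 entry 9 fell and 3 rose (adjusted p = 0.12), with Ccnd3, a D cyclin, at 8.39 ± 0.536 against 52.6 ± 18.1 RPKM. Of the 10 genes of the cyclin-dependent kinase inhibitor list 3 rose and 5 fell (adjusted p = 0.59). Among them Cdkn2b rose by 1.69, and Cdkn1c, Cdkn2d and Cdkn1a fell with log2 changes of -2.66, -1.58 and -1.41. Of this list 1 rose and 5 fell without Tubastatin A replicate 2.

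Of 11 measured Notch genes all fell (adjusted p = 6.6e-05; adjusted p = 0.36 with an estimated correlation), among them the receptor Notch3 at 1.19 ± 0.281 against 39.9 ± 17.5 RPKM. Of the 14 myogenic regulators 10 fell and 1 rose (adjusted p = 0.0065; adjusted p = 0.14 with an estimated correlation). Myf5 fell from 248.4 ± 30.7 to 6.37 ± 0.542 RPKM, Id2 and Id3 fell with log2 changes of -1.67 and -3.58, and Myod1 did not pass (adjusted p = 0.56) but fell with a log2 change of -0.89, without fresh replicate 1. Myog fell with a log2 change of -3.33 (adjusted p = 0.028), with Tubastatin A replicate 2 above every fresh library. That call ended without any single fresh library, or without Tubastatin A replicate 1, 3 or 4, each time with replicate 2 kept in. Myog stood at 195.2 RPKM in replicate 2 and at 1.68 to 2.05 RPKM in the other Tubastatin A libraries. The fresh libraries held 68.7 to 96.5 RPKM. Of 20 measured differentiation genes 1 rose and 5 fell, none and 4 adjusted over the list alone (adjusted p = 0.79), and none rose and 12 fell without replicate 2. Desmin fell with a log2 change of -1.90. C1qtnf3, a secreted relative of complement, fell with a log2 change of -6.08 (SE 0.92, adjusted p = 1.1e-04), at 60.7 RPKM in replicate 2 and between 1.17 and 1.62 RPKM in the other 3.

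Immediate early, cytokine, heat shock and matrix genes stayed below fresh levels with Tubastatin A. Of 20 measured immediate early genes 18 fell and 1 rose (adjusted p = 1.1e-09; adjusted p = 0.19 with an estimated correlation), with Fos, Egr2 and Nr4a1 lower at log2 changes of -7.80, -6.01 and -6.45. Of 18 measured NF-kB and cytokine genes 17 fell and 1 rose (adjusted p = 4.2e-08; adjusted p = 0.12 with an estimated correlation), with Cxcl1, Bcl3 and Birc3 lower at log2 changes of -7.23, -4.59 and -4.38. Of the 15 heat shock genes 13 fell and 1 rose (adjusted p = 7.6e-04; adjusted p = 0.50 with an estimated correlation), and the gene that rose was Hspb8, by 2.47. Of 23 measured matrix genes 21 fell and none rose (adjusted p = 5.6e-07; adjusted p = 0.40 with an estimated correlation), with Bgn and Sparc, a matrix glycoprotein, lower at log2 changes of -4.09 and -3.42. Cebpd, a stress-responsive transcription factor, and Erfe, the hormone erythroferrone, were among the 10 with the largest fall at mean levels of at least 4 on the log2 scale, with log2 changes of -6.30 (SE 0.15) and -7.72 (SE 0.18).

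Of the 13 tubulins 9 rose and 3 fell (adjusted p = 0.027; adjusted p = 0.51 with an estimated correlation), with Tuba1b, Tubb5, Tubg1, a gamma-tubulin, and Tuba8 higher by 1.46, 1.10, 1.29 and 0.93. Above the same mean level of 4 the 10 genes with the largest rise included Me1, the malic enzyme, at 66.1 ± 1.02 against 1.41 ± 0.408 RPKM, Pgd, of the pentose phosphate pathway, higher by 3.66 (SE 0.10) from 5.43 ± 0.650 RPKM, and Gsr at 138.4 ± 6.40 against 10.6 ± 0.948 RPKM. Blvrb, a biliverdin reductase, Esd, an esterase, Lgals3, a galectin, Asns, Mllt11 and Slc48a1 rose by between 3.26 and 4.49. Of the 18 glycolysis genes 9 rose and 5 fell (adjusted p = 0.13), with Gpi1, a glycolytic isomerase, higher by 2.09. Of the 30 ribosome biogenesis genes 11 rose and 3 fell (adjusted p = 0.33), and of the 28 measured genes of oxidative phosphorylation 3 rose and 3 fell (adjusted p = 0.93), with Ndufa4, of the respiratory chain, higher by 2.04. Without fresh replicate 1 these lists had 9 higher and 9 lower and 3 higher and 9 lower, and the median of the ribosome list turned from 0.10 to -0.18. Ctsd stood at 451.4 ± 44.6 against 81.9 ± 8.19 RPKM and Sqstm1 at 1529 ± 76.1 against 1611 ± 382.0 RPKM.

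Several further lists turned with the scaling in this comparison, which shifted all genes by 0.688 when reads alone were used. Of the 23 autophagy and lysosome genes 7 rose and 11 fell (adjusted p = 0.96), against 13 higher and 2 lower with reads alone. Of the 17 genes of the integrated stress and unfolded protein response 5 rose and 10 fell (adjusted p = 0.67), against 7 and 6. Of the 20 cholesterol synthesis genes 4 rose and 10 fell (adjusted p = 0.38), against 6 and 3, with Idi1 and Hmgcs1 lower at log2 changes of -1.51 and -1.55. Of the 21 translation factors 4 rose and 8 fell, 3 and 7 adjusted over the list alone (adjusted p = 0.96), against 11 and 2. Of the 40 primary cilium genes 11 rose and 14 fell (adjusted p = 0.96), against 25 and 4, with Arl13b lower at a log2 change of -3.45. Of the 18 measured genes of fatty acid oxidation 5 rose and 6 fell (adjusted p = 0.97), against 13 and 1, and of the 14 deacetylase and tubulin acetylation genes 2 rose and 7 fell (adjusted p = 0.26), against 5 and 4. Of the 8 genes of cilium disassembly 1 rose and 3 fell (adjusted p = 0.42), of the 10 measured Hedgehog genes 1 rose and 5 fell (adjusted p = 0.22), and of the 18 p53 targets 9 rose and 8 fell, 10 and 8 adjusted over the list alone (adjusted p = 0.65).

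Markers of other cell types were lower with Tubastatin A than in fresh cells, as with vehicle. Of these markers 9 of 9 endothelial, 4 of 5 immune, 9 of 11 fibro-adipogenic, 6 of 7 tenocyte, 9 of 9 pericyte and smooth muscle, 4 of 5 Schwann cell and 8 of 12 myofibre markers fell, 9 of the last adjusted over the list alone, and 1 Schwann cell marker rose. All but the immune list (adjusted p = 0.070) passed, with adjusted p between 6.5e-05 and 0.039, and with adjusted p between 0.12 and 0.66 with an estimated correlation. Both erythroid markers fell. Dpt, a dermal matrix protein of fibroblasts, Pecam1 and Actn3, the actinin of fast fibres, fell with log2 changes of -5.31, -2.41 and -3.12, and without replicate 2 all 12 myofibre markers fell.

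Median and mean log2 change differed in sign for muscle differentiation (0.02 and -0.49), translation factors (0.01 and -0.16), oxidative phosphorylation (-0.05 and 0.02) and p53 targets (0.41 and -0.12), and the camera direction was up for fatty acid oxidation and the primary cilium although their medians were -0.06 and -0.01.

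By scaling, the split was 6910 higher and 2594 lower with reads alone, 6480 and 2788 without the 10 most abundant and the mitochondrial genes, and 4601 and 3851 with upper quartile factors. Without Tubastatin A replicate 2, 7801 genes passed, and without fresh replicate 1, 8476. Only 1 of the 35 splits of the libraries gave as many genes, the real split, and the highest other split gave 33. The groups did not overlap for 61.3% of genes, where 5.70% would do so by chance.

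Many genes that culture changed differed in the opposite direction with Tubastatin A. Of the 8580 genes that differed between vehicle and fresh, 4640 differed between Tubastatin A and vehicle in the opposite direction and 909 in the same direction. Without Tubastatin A replicate 2 the opposite genes numbered 4297, without fresh replicate 1 they numbered 4911, and with reads alone as the scaling 2915 of them were lower and 1644 higher with Tubastatin A. Of the 4096 genes that rose in culture, 59.8% were lower with Tubastatin A than with vehicle, among them Mcm5, Uhrf1, Cdk1 and Ccnd1. Of these 2448 genes, 1161 did not differ from fresh, 501, Mcm5 and Ccnd1 among them, lay below it and 786 stayed above. Of the 4484 genes that fell in culture, 48.9% were higher with Tubastatin A, among them Ddit3, Sqstm1 and Atf3, and of these 2192 genes 828 did not differ from fresh, 335 lay above it and 1029 stayed below. With independent lists of these sizes, 1215 and 1329 opposite genes would overlap. The covariance across genes of both log2 changes was -0.577, against -0.016 in 100 simulated sets with Tubastatin A at vehicle levels, a difference of -0.561. The vehicle level itself enters both comparisons, so a Tubastatin A state unrelated to fresh would also give many opposite genes. The independent lists, simulated sets and divided libraries do not account for this, so these values alone do not show movement toward fresh. Both comparisons also share the 3 vehicle libraries. With these divided in 6 ways, 1 library for one comparison and 2 for the other, 3240 to 3612 genes were opposite and 499 to 613 the same, and the covariance lay between -0.580 and -0.556.

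Tubastatin A also took genes away from both other groups. In all, 3404 genes differed from fresh and from vehicle in the same direction, 1740 higher and 1664 lower, where independent lists would give 1130 and 1336. With reads alone as the scaling 2947 were higher and 901 lower, and without Tubastatin A replicate 2 both together numbered 3034. Uchl1, Ctsd, Hspb8, Tuba8, Cdkn2b and Hadh were higher than in both, and Vcam1, Myf5, Pax7, Gas1, Mcm5, Ccnd1 and Atat1 were lower than in both. The covariance was 0.194 against 0.0124 in 100 simulated sets with all groups at 1 level, a difference of 0.182. The correlation was 0.207 against 0.428 in these sets. The Tubastatin A level itself enters both comparisons, so a state unrelated to fresh and vehicle would also give many genes in the same direction. The independent lists and simulated sets do not account for this, nor does dividing libraries. Both comparisons also share the 4 Tubastatin A libraries. With these divided in 6 ways into 2 and 2, 2598 to 2673 genes differed in the same direction and 1267 to 1368 in opposite ones, and the covariance lay between 0.177 and 0.194.

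**Figure D4:**
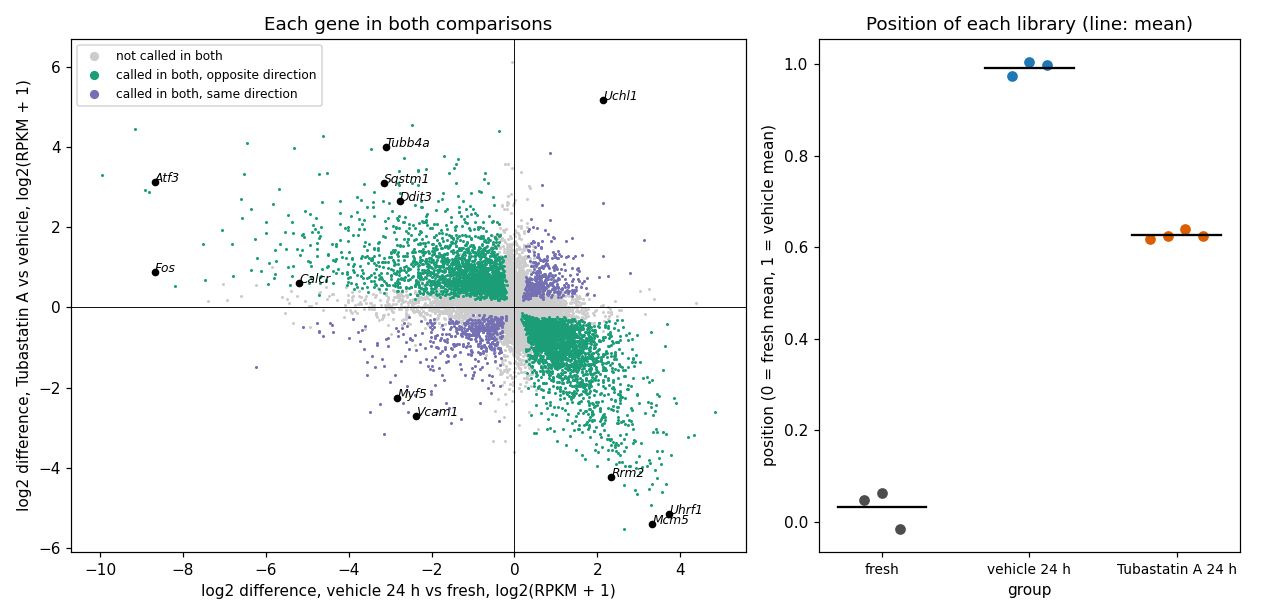
Left, log2 difference of each gene for vehicle against fresh (horizontal) and for Tubastatin A against vehicle (vertical), with 4640 genes called in opposite and 909 in the same directions; right, the position of each library on the axis from the fresh mean (0) to the vehicle mean (1), with lines at group means. The Tubastatin A libraries sat between 0.618 and 0.639.

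Libraries were placed on the axis across all genes from fresh to vehicle, each fresh or vehicle library on an axis made without it. Tubastatin A libraries, which do not enter the axis, lay at 0.626 ± 0.009 (SD, n = 4). Fresh libraries lay at 0.031 ± 0.041 (n = 3) and vehicle libraries at 0.992 ± 0.016 (n = 3). In an exact two-sided permutation test the Tubastatin A group differed from each other group with p = 0.057, the smallest p that 3 against 4 libraries allow. The median position was 0.45 for genes that rose in culture and 0.70 for those that fell. Of the squared difference between Tubastatin A and fresh, 52.1% lay along this axis and the rest outside it. The fresh and vehicle means set 0 and 1 of the axis. A Tubastatin A state unrelated to either could therefore also lie between them and reach this p. The positions, their medians and this share alone thus do not show movement toward fresh. The root mean square log2 difference was 1.24 for vehicle against fresh, 0.88 for Tubastatin A against vehicle and 1.08 for Tubastatin A against fresh.

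On the mouse genome build mm10, Hdac6 (ENSMUSG00000031161) lies on chromosome X from 7930120 to 7947889, Pax7 (ENSMUSG00000028736) on chromosome 4 from 139737062 to 139833528, Vcam1 (ENSMUSG00000027962) on chromosome 3 from 116109949 to 116129688, Mcm5 (ENSMUSG00000005410) on chromosome 8 from 75109569 to 75128439, Sqstm1 (ENSMUSG00000015837) on chromosome 11 from 50199366 to 50210827 and Uchl1 (ENSMUSG00000029223) on chromosome 5 from 66676091 to 66687234, all protein-coding genes.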

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

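Of the tests in this part, those of other splits, of Tubastatin A replicate 2, of fresh replicate 1 and of scaling were chosen after the results were seen, while the test of gene length and GC content was set beforehand.

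Among the 4 Tubastatin A libraries, 21 of 217 values set a single library far from the other 3, by the gap to its nearest neighbour as a share of the whole range, where chance sets apart about 1 in 20 groups, or 10.9 values. Replicate 2 was the far library in 11 of them, replicates 1, 3 and 4 in 2, 5 and 3. The share was 0.998 for Myog, at 195.2 RPKM against at most 2.05 in the others, 0.993 for Acta2, at 60.75 against at most 10.67, and 0.992 for C1qtnf3, at 60.65 against at most 1.624. For medians of lists in replicate 2 it was 0.95 for muscle differentiation, 0.940 for mature myofibre markers, 0.926 for myogenic regulators and 0.845 for Schwann cell markers. Replicate 2 also held the highest Mki67 (0.90), Exo1 (0.863), Cdk1 (0.856) and Plk1 (0.852).

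Muscle differentiation genes in replicate 2 were weighed first. Fragments of mature fibres would bring other abundant fibre transcripts, but the median of the 11 other myofibre markers was 2.045 RPKM beside 311.0 RPKM of Acta1, which argues against them as the source. Mixing with a fresh or vehicle library, or a wrong label of one, would keep values within the range of those libraries, but 66.7% of the 81 genes that stood out (54) lay above every fresh and vehicle library. Some cells of this single animal that went on to differentiate are a candidate explanation, as a hypothesis that was not tested further. Contamination from another culture was not tested either.

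Immediate early and heat shock genes in fresh replicate 1 were weighed next, with 17.9% of reads against 10.03% and 9.24%. The median difference of that library from the other fresh libraries was 0.01 over all genes and 0.66 over both lists. A wrong scaling would move all genes. But the values already carry the authors' scaling, which may have set the bulk of genes level beforehand, so the small median cannot decide this. The values show only that both lists lay above the bulk of genes in that library. Longer or harsher handling of that animal's tissue may explain it and was not tested, since the labels used here give no handling times.

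Quiescence genes stayed below fresh levels with Tubastatin A while cell cycle genes fell, which was the last pattern weighed. Under 4 other scalings the median log2 change of quiescence genes against fresh was -2.16 at the highest, and against 100 genes matched on length and GC content it was -2.76, which argues against scaling, length and GC content. Loss of both programmes in the same cells may explain the pattern as a hypothesis, but a loss of some cells in culture, or the stress of sorting in fresh cells, stays open and was not tested.

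Only 1 of the 35 splits gave as many genes for Tubastatin A against vehicle (7594, the highest other split 27). The same held for 1 of the 35 for Tubastatin A against fresh (8314, the highest other 33). This is the smallest share that 35 splits can give, and splits that mix the groups widen the spread within them. The result thus speaks against chance in forming these groups without excluding it. For vehicle against fresh 1 of the 10 splits gave as many genes (8580, the highest other 0), and 10 splits are too few for a share under 0.05.

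The other values that set a library apart were as follows. Replicate 3 stood apart for Calcr (0.871, 1.841 RPKM against 2.446 to 2.536), Cd34 (0.919, 2.60 against 3.705 to 3.802), G6pdx (0.914, 41.19 against 40.02 to 40.12), Mllt11 (0.957, 54.32 against 83.17 to 84.46) and reads over scaled size (0.869, 0.834 against 0.887 to 0.895). Replicate 4 stood apart for Kif3a (0.895, 21.27 RPKM against 20.02 to 20.16), Rgs5 (0.860, 0.1774 against 0.07774 to 0.09168) and Hba-a1 (1.0, 0.09934 against a floor of 0.01112 in the others). Replicate 1 stood apart for Pecam1 (0.851, 0.1905 RPKM against 0.2396 to 0.2483) and Mcam (0.872, 2.818 against 2.029 to 2.13).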

How the results depend on the processing

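The voom fits without weights, and for overlaps the division of shared libraries and the weights, were chosen after the results were seen. The same holds for leaving Tubastatin A replicate 2 out of the variance of vehicle against fresh. It also holds for weights and reads-alone scaling, where run, for positions, list tests and named genes. The reads-alone scaling for overlaps was planned. Counts of changed genes stayed within 1.5 times under every alternative run except a 2-fold minimum. By its construction that left 3916, 2402 and 3062 genes in the order of the comparisons. It also left 1310 genes opposite in culture and with Tubastatin A, and 720 changed against both groups. With a library left out, the counts ranged over 7868 to 8912, 6588 to 7133 and 7768 to 8540 genes. They ranged over 3971 to 5168 for opposite genes, 2950 to 3681 against both, and 49 to 51 list tests. The position of Tubastatin A libraries moved by more than its spread to 0.66 with genes of a mean log2 of at least 4, 0.61 with genes scaled to their spread, 0.60 and 0.658 with pseudocounts of 0.1 and 5, and ranged over 0.617 to 0.633 with a library left out, where the lowest value left out vehicle replicate 1; the cause was not tested. Camera with an estimated correlation called 0 list tests against 49, with 22 at an unadjusted p under 0.05. Fry called 74, all 49 among them. For Tubastatin A against vehicle the estimated correlation was 0.21 in the S phase list but 0.01 in the G1 entry list, as preset. The adjusted p of the G1 entry list still went from 9.4e-06 to 0.12. A higher correlation thus does not account for the loss in that list, and the cause was not tested. Named genes gave 318 results for 177 genes, and none reversed: 1891 alternatives and 2107 with a library left out kept direction and side of the threshold, 5 and 8 lost the call and 9 and 7 gained it. With Tubastatin A replicate 2 out of the shared variance, vehicle against fresh had 4001 genes higher and 4377 lower, and of the 177 named genes Myog gained and Hadh lost its call. A block for the replicate number gave 8503, 7136 and 7888 genes, 4412 opposite genes, 3086 against both and 50 list tests. Only 5 of 9 same-number pairs correlated over 0.1 (from -0.23 to 0.48), and 7 of 24 pairs with different numbers did, so whether the numbers pair the libraries stays uncertain. DESeq2 fits were not run, since the deposited values are RPKM. The fit without a filter on low levels is the one reported. Depth limits genes near the floor, where 1 read in 1 kb equals 0.016 to 0.0339 RPKM.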

Other observations

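Of 7 genes of the antioxidant response outside the fixed lists, 4 rose with Tubastatin A, 1 fell and 2 did not pass. Srxn1, which restores peroxiredoxins, rose from 65.2 ± 2.28 RPKM in vehicle to 572.5 ± 27.1 RPKM (log2 change 3.11, SE 0.35, adjusted p = 1.2e-05), Hmox1, the haem oxygenase, by 2.34, Gclm, of glutathione synthesis, by 1.25 and Slc7a11, the cystine transporter, from 0.838 ± 0.166 to 4.20 ± 0.582 RPKM. Nqo1, a quinone reductase, fell with a log2 change of -0.61, and Gclc and Txnrd1 did not pass. Kif1a, an axonal motor, rose from 0.00191 ± 6.95e-04 to 4.19 ± 1.10 RPKM, and Ina, a neuronal filament, by 0.44. The vehicle value of Kif1a lay below the 0.0208 to 0.0233 RPKM that 1 read in 1 kb gives in vehicle libraries. That value is thus near the floor, and no fold can be taken from it. The 7 antioxidant genes, Kif1a and Ina were chosen after their values were seen. The tests below used other genes, listed before their values were examined.

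A first hypothesis was that Tubastatin A cultures raise the activity of NRF2, the transcription factor of the antioxidant response, with more than 50% of 18 further targets higher than in vehicle. Of these 9 were higher, 2 lower and 7 not called, 11 and 2 adjusted over the list alone, with a median log2 change of 0.59, so the bound was not met over all genes but was over the list alone. Camera, adjusted over the 6 tests of both hypotheses, gave an adjusted p of 0.037 at a preset correlation and of 0.38 with an estimated one. Against fresh cells 12 were higher and 4 lower, with a median of 1.29 (adjusted p = 0.0038; adjusted p = 0.30 with an estimated correlation). Vehicle against fresh had the same counts, 12 and 4, with a median of 0.76 (adjusted p = 0.039; adjusted p = 0.38 with an estimated correlation). Osgin1, a growth inhibitor, Mgst1, a glutathione transferase, and Taldo1, of the pentose phosphate pathway, rose by 2.94, 2.61 and 1.72, and Tkt, of the same pathway, fell with a log2 change of -1.12. With 9 members higher, the test of NRF2 activity did not meet the bound set beforehand, and by that bound it went against the hypothesis. Such activity is left open only by a rule made after the results were seen, since the count over the list alone passed.

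A second hypothesis was that Tubastatin A may release genes typical of neurons, as seen for Uchl1 and Kif1a. Of 33 such genes 16 were measured, and 12 were higher than in vehicle and 2 lower, with a median log2 change of 0.57 (adjusted p = 0.0038; adjusted p = 0.090 with an estimated correlation). Kif5c, a neuronal kinesin, rose from 0.353 ± 0.196 to 4.09 ± 0.560 RPKM, and Dnm1, a synaptic dynamin, Mapk8ip1, a kinase scaffold, and Syn1, of synaptic vesicles, rose by 1.78, 1.71 and 1.05, while Nsg1 and Cplx2 fell. Against fresh cells 9 were higher and 4 lower (adjusted p = 0.037; adjusted p = 0.19 with an estimated correlation). The bound set beforehand was met by these 12 of 16, but not by 12 of all 33. Genes with low levels may be in the table only because Tubastatin A raised them: of 1886 genes under 1 RPKM in both fresh and vehicle cells 718 were higher and 218 lower. Of the neuron-type genes 10 were of this kind, 7 higher and 1 lower, and of the other 6, 5 were higher and 1 lower, in a check made after the results were seen. A release of neuron-type genes therefore stays open, also by a rule made after the results were seen. A direct effect on deacetylases was not tested.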
